A study of Mus musculus with 4 samples.

How the data were processed

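The study profiled CD45.2-positive cells that excluded propidium iodide from B16-GP33 melanomas of C57BL/6 mice, per the labels' protocols, in 4 libraries: control IgG, anti-PD-1, anti-PSGL-1 and both antibodies. Tumours were dissociated with enzymes and the cells sorted before capture on the 10x Genomics Chromium platform, per the labels' protocols. The values deposited by the authors are raw UMI counts per gene and barcode for 27998 genes, with no normalisation. Reads were processed with Cell Ranger 3.1.0 on mm10 and FastQC was used, per the submitters' processing notes; the gene annotation version and the FastQC version are not given in the sources used here. A UMI marks an original RNA molecule, so copies made by amplification count once. Groups came from the treatment labels, with 1 library per group. Without replicates within a group, no p-value, standard error or count of changed genes was computed from cells. T cell receptor V gene use was planned and was not analysed here, because the feature lists used hold no receptor V genes. Values of some single genes that the naming rule picked are not reported here.

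Cells were kept with at least 300 detected genes, at most 10% mitochondrial UMIs and at most 60000 UMIs. This left 9465, 5238, 6869 and 4382 cells in the IgG, anti-PD-1, anti-PSGL-1 and combination libraries. Scrublet, as built into scanpy, scored likely doublets in each library; its own threshold called 1, 104, 0 and 54 cells and had not worked, so the highest-scoring cells were removed at a fixed share of 0.8% for each 1000 cells (717, 219, 377 and 154 cells). Median detected genes per kept cell were 1411, 1938, 1898.5 and 2390 and median mitochondrial shares 2.47%, 2.23%, 2.38% and 2.21%. Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes, 30 principal components and a graph of 20 neighbours entered Leiden clustering at resolution 1 with seed 0 (Python 3.11.15, scanpy 1.11.5, leidenalg 0.10.2, igraph 0.11.9, scikit-learn 1.9.0, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, matplotlib 3.10.9). No batch correction was applied. The 25 clusters were named from marker lists fixed before the data were examined, and T and NK cells were clustered again into 20 clusters, giving 13 named classes. A name needed at least 3 of the class's markers in at least 10% of the cells and at 1.5-fold or more over the median cluster, with fewer than 25% of cells mixed between lineages. CD8 T-like clusters needed Cd8a or Cd8b1 in 60% of cells and Cd4 in at most 20%, CD4 T-like clusters Cd4 in 40% and Cd8a or Cd8b1 in at most 20%, and regulatory T-like clusters Foxp3 in 50%. These naming thresholds were set after the data were seen; the CD8 minimum was lowered so that the naive-like cluster was taken in. Clusters that did not meet them stayed as other T or unnamed cells. Among other T were a cluster led by Ifit1 and Ifit3, with Cd8a or Cd8b1 in 52.8% of cells, and a cluster led by Hspb1 and Hspa1a, at 57.9%. A further other T cluster, led by Ccl1 and Csf2, had Cd8a or Cd8b1 in 74.2% of cells and was left out for Cd4 in 28.4%. Ifng of the cytotoxic effector list and Xcl1 of the progenitor and memory list were among its leading genes. All values of CD8 T-like cells therefore leave these clusters out, including the type I interferon and dissociation stress lists.

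Raw UMIs were summed per class and library and given as CPM of the class, that is, scaled to the total UMIs of the class in that library. Values have exact 95% Poisson intervals, shares exact 95% binomial (Clopper-Pearson) intervals, and ratios of CPM between 2 libraries exact conditional 95% intervals, given in parentheses or after the ratio. Comparisons were each treated library with IgG and the combination with each single antibody, 5 in all. CD8 T-like cells and macrophage- and monocyte-like cells (summed together) are described by genes; NK-like, conventional CD4 T-like and cDC2-like cells, which also had at least 100 cells in every library, by gene lists. Genes were named by a rule fixed before the data were examined: for each comparison the 5 genes higher and 5 lower with the largest ratio, ranked by the interval bound nearest to 1, among genes at 50 CPM or more in either library, then Pdcd1, Selplg and up to 2 members of each list each way. The rule left out receptor, immunoglobulin, mitochondrial, ribosomal protein, haemoglobin and sex-linked genes, predicted gene models, and melanoma, erythroid and keratinocyte markers. The genes drawn in the plots, and those given for a comparison in which the rule did not name them, were chosen after their values were seen. The 14 gene lists were inhibitory receptors and exhaustion, progenitor and memory, cytotoxic effector, T cell receptor response, cell cycle, regulatory T cell programme, type I interferon response, interferon-gamma response and antigen presentation, tumour macrophage, myeloid inflammation, hypoxia and glycolysis, selectin ligand pathway, chemokine receptors and homing, and dissociation stress. A list is summarised by the median log2 ratio of members with at least 20 UMIs in both libraries together, and by the percentile of that median among 10000 random lists matched on size and mean expression. A member with 0 UMIs in a library entered at its bound from a floor of 3 counts. The counts of members at 1.5-fold or more were a size chosen after the data were seen. Of the listed genes, 1 inhibitory gene symbol and 1 inflammation gene symbol were not among the features; the latter, Acod1, is listed as Irg1 and was left out of the list. Some genes stand in more than 1 list, such as Gzmb, Tnf and Nos2.

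Shares of cells with a UMI of a gene were compared after each cell was thinned to 2000 UMIs. The 8 genes shown were chosen from the fixed lists after their CPM had been seen. To test depth per cell, equal numbers of cells of the anti-PD-1 and IgG libraries were drawn from each of a series of narrow UMI ranges within a class. Sequence shared between genes was measured on GENCODE vM21 transcripts as the share of 50-base words in a gene's last 500 bases that occur in another gene. 8809 of 8817 well-counted genes were matched by gene ID. Coordinates are from the same annotation (mm10, 1-based). The statistics were tested on simulated data for CD8 T-like cells, combination against IgG, with 200 of 11033 genes changed. The simulated counts held counting error only, without variation between cells, mice or libraries, and the simulated lists were random genes. The rates that follow thus check the calculation and are not error rates for a comparison of treatments. The ratio's interval held the simulated ratio in 95.5% of genes, the whole interval lay on the right side of 1 in 89% of 100 genes changed 2-fold and 98% of 100 changed 4-fold, and 4.84% of 10833 unchanged genes had an interval without 1. All 10 genes named there were changed in the simulation. Of 100 simulated unchanged lists, 94 lay between percentiles 2.5 and 97.5, and of 100 lists shifted by a log2 ratio of 0.5, 100 lay above percentile 97.5. The 26 alternatives fixed before the data were examined covered cell filters, doublets, resolution, naming, thinning, scaling, cell weights, count filters and list summaries; 3 more were added after seeing the data.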

Results

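Live immune cells were sorted from mouse melanomas as cells that excluded propidium iodide and carried CD45.2, a pan-leukocyte marker, and were profiled with droplet-based single-cell RNA sequencing (10x Genomics). The tumours were B16-GP33, a C57BL/6 melanoma line that carries GP33, a viral peptide recognised by CD8 T cells, grown under the skin for 18 days. Mice received a control IgG, an antibody against PD-1, an antibody against PSGL-1, or both antibodies, at 200 ug of each antibody on days 8, 10 and 12. PD-1 is an inhibitory receptor of activated T cells, and PSGL-1 is a selectin ligand of leukocytes with a reported inhibitory role in T cells. The comparisons ask how the tumour's immune cells differed when either receptor, or both, had been targeted. Each of the 4 groups was a single library, so the differences have no replicate check and no test between groups was possible. Every interval covers counting error only. The libraries held 27270 barcodes and 184611085 UMIs. There were 9733 barcodes and 45411218 UMIs with IgG, 5621 and 40913129 with anti-PD-1, 7302 and 53303195 with anti-PSGL-1, and 4614 and 44983543 with the combination. After filtering, 24487 cells were kept (8748, 5019, 6492 and 4228 in the same order), with median depths of 3679, 6252, 6166 and 8402.5 UMIs per cell. Transcripts of 10 melanoma genes made up 28.6, 23.5, 18.9 and 13.9 CPM (counts scaled to the UMI total) of all kept cells and 91.6, 49.0, 45.19 and 36.2 CPM in macrophage- and monocyte-like cells. Other values did not follow this order. Pmel alone was at 2.78, 2.84, 2.07 and 2.51 CPM of all kept cells. In CD8 T-like cells the 10 genes made up 1.07, 2.36, 1.12 and 2.09 CPM.

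The genes of the antibody targets were examined first. An antibody against the protein need not alter the RNA, so these values do not check the labels. Pdcd1 (ENSMUSG00000026285, chromosome 1, 94038305 to 94052553 in mm10, protein coding) encodes PD-1. In CD8 T-like cells it stood at 465 (450.3 to 479.5) CPM with IgG, 602 (588 to 616) with anti-PD-1, 434 (422 to 446) with anti-PSGL-1 and 641 (630.3 to 652) with the combination. Against IgG these were ratios of 1.30 (1.25 to 1.35), 0.933 (0.895 to 0.973) and 1.38 (1.33 to 1.43). Conventional CD4 T-like cells carried less Pdcd1, at 117, 196, 121 and 255.6 CPM in the order IgG, anti-PD-1, anti-PSGL-1 and combination. Macrophage-like cells carried 2.83, 3.195, 2.96 and 4.11 CPM. Selplg (ENSMUSG00000048163, chromosome 5, 113818536 to 113832644, protein coding) encodes PSGL-1 and was more even, at 469, 446, 462 and 482 CPM in CD8 T-like cells. It was highest in NK-like cells (874, 881, 665 and 709 CPM) and lower in cDC2-like cells (267, 319, 238 and 249 CPM), monocyte-like cells (233, 224, 233 and 246 CPM) and macrophage-like cells (115, 115, 102 and 125 CPM). Conventional CD4 T-like cells held 567, 544, 413 and 511 CPM of Selplg.

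The immune infiltrate differed in its main classes of cells. CD8 T-like cells made up 15.1% (14.3 to 15.8) of kept cells with IgG, 21.2% (20.1 to 22.4) with anti-PD-1, 19.9% (19.0 to 20.9) with anti-PSGL-1 and 39.4% (37.9 to 40.8) with the combination. Macrophage- and monocyte-like cells together made up 26.3% (25.4 to 27.2), 48.1% (46.7 to 49.5), 35.4% (34.3 to 36.6) and 37.1% (35.6 to 38.5) in the same order, so that the anti-PD-1 library was the richest in them. Regulatory T-like cells, the suppressive CD4 subset that expresses Foxp3, were fewest with the combination, at 1.77% (1.40 to 2.22) against 5.38% (4.92 to 5.88) with IgG, 2.43% (2.02 to 2.90) with anti-PD-1 and 3.74% (3.29 to 4.23) with anti-PSGL-1. Conventional CD4 T-like cells held 3.92%, 2.13%, 6.36% and 3.22%, with the highest share in the anti-PSGL-1 library.

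**Figure D1:**
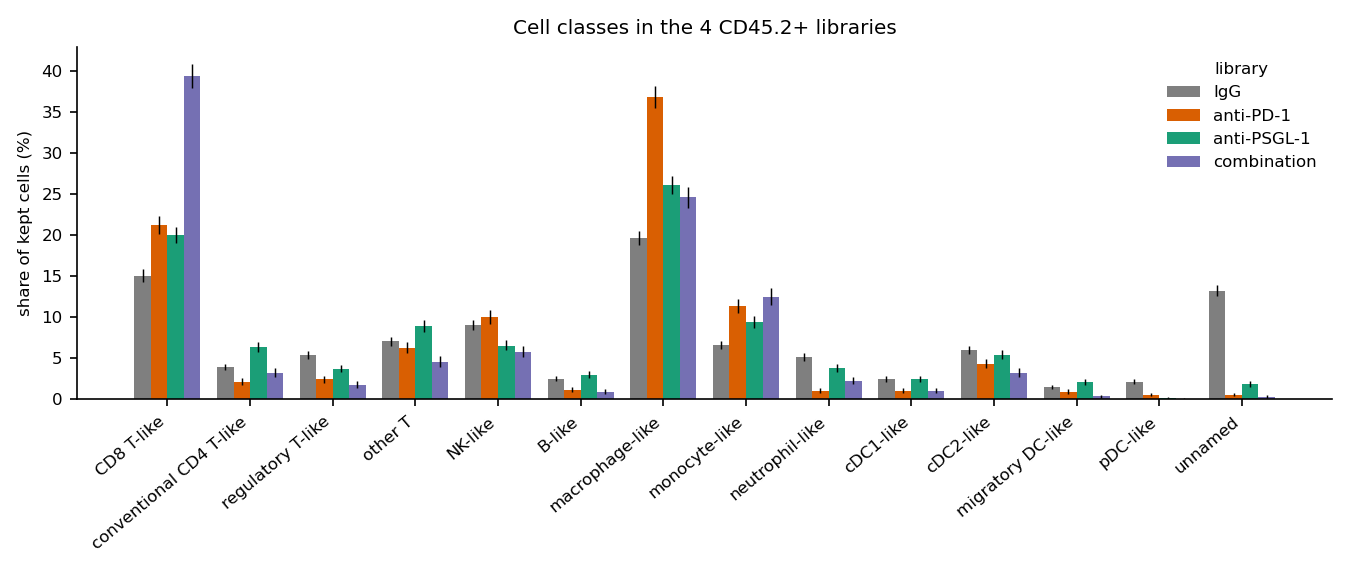
Share of kept cells (percent, linear axis) of each class of cells in the IgG, anti-PD-1, anti-PSGL-1 and combination libraries, with exact 95% binomial intervals that cover counting error only. CD8 T-like cells stand at 39.4% in the combination library and at 15.1% with IgG, and unnamed cells at 13.2% with IgG.

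Among the other lymphoid cells, NK-like cells held 9.09%, 10.0%, 6.55% and 5.79% and B-like cells 2.51%, 1.12%, 2.99% and 0.946%. Macrophage-like cells alone held 19.7%, 36.8%, 26.0% and 24.6% and monocyte-like cells 6.61%, 11.3%, 9.40% and 12.5%. Neutrophil-like cells were at 5.14%, 1.08%, 3.84% and 2.27%. Among dendritic cells, cDC1-like cells (the subset that cross-presents antigen to CD8 T cells) held 2.49%, 1.06%, 2.45% and 1.06%, cDC2-like cells 5.97%, 4.30%, 5.39% and 3.19% and migratory dendritic-like cells 1.52%, 0.917%, 2.14% and 0.355%. Plasmacytoid dendritic-like cells, producers of type I interferon, were at 2.14% (1.84 to 2.46) with IgG, 0.558% (0.371 to 0.805) with anti-PD-1, 0.185% (0.0955 to 0.323) with anti-PSGL-1 and 0.0237% (0.000599 to 0.132) with the combination. Mast- or basophil-like cells held 0.217%, 0.219%, 0.2002% and 0.0710%. T cells of no assigned subset held 7.05%, 6.28%, 8.92% and 4.59% and cells of no assigned class 13.2%, 0.558%, 1.85% and 0.284%. Both groups were set apart by naming thresholds that were fixed after the data were seen. All of these are shares of the live CD45.2 sort, and the libraries also differed in depth per cell and in barcodes removed as likely doublets (7.58%, 4.18%, 5.49% and 3.51%).

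Within the T-like cells the balance lay furthest towards CD8 in the combination library. CD8 T-like cells were 47.9% (46.0 to 49.8) of T-like cells with IgG, 66.2% (63.8 to 68.5) with anti-PD-1, 51.2% (49.2 to 53.2) with anti-PSGL-1 and 80.4% (78.6 to 82.1) with the combination. Regulatory T-like cells were 17.1%, 7.58%, 9.60% and 3.62% of T-like cells, conventional CD4 T-like cells 12.5%, 6.65%, 16.3% and 6.57%, and other T cells 22.5%, 19.6%, 22.9% and 9.38%. After every cell was thinned to 2000 UMIs, Gzmb, a granzyme of cytotoxic granules, was detected in 48.9%, 77.3%, 53.4% and 83.5% of CD8 T-like cells in the order IgG, anti-PD-1, anti-PSGL-1 and combination. Prf1, the pore-forming perforin, was detected in 19.4%, 41.5%, 18.2% and 39.2%. Gzmf was detected in 2.30%, 20.8%, 2.04% and 18.1%, Gzmk in 22.4%, 14.2%, 24.4% and 30.2% and Pdcd1 in 45.6%, 62.1%, 47.5% and 65.6%. Tcf7, which encodes the TCF-1 factor of naive and progenitor T cells, was detected in 15.2%, 4.73%, 10.5% and 3.22%. Slamf6, a surface marker of progenitor exhausted cells, was in 7.61%, 3.50%, 5.42% and 4.25%. Tox, a factor of exhausted T cells, was nearly even at 32.6%, 31.2%, 32.0% and 34.1%. In macrophage- and monocyte-like cells, taken as background, the same thinning gave 0.824%, 2.58%, 1.59% and 2.43% for Gzmb and 0.194%, 0.350%, 0.0469% and 0.526% for Prf1. It gave 0.533%, 0.525%, 0.281% and 0.724% for Pdcd1, 0.242%, 0.131%, 0.281% and 0.0658% for Tcf7 and 1.84%, 2.23%, 1.5002% and 1.71% for Slamf6. The highest background share of any library was 0.0970% with IgG for Gzmk, 0.394% with anti-PD-1 for Tox and 0.987% with the combination for Gzmf. Thinning left out 56, 7, 22 and 16 shallower CD8 T-like cells and 237, 131, 168 and 47 background cells. The median depths before thinning were 4979, 10333, 7492 and 11006 UMIs in CD8 T-like and 4919, 6416.5, 6957 and 8140 UMIs in background cells. Unthinned CD8 shares were 61.2%, 87.1%, 71.6% and 92.2% for Gzmb, 37.4%, 73.5%, 43.1% and 71.2% for Prf1, 3.34%, 29.8%, 3.09% and 25.7% for Gzmf and 41.2%, 34.5%, 51.0% and 63.6% for Gzmk. They were 62.3%, 87.3%, 70.9% and 91.0% for Pdcd1, 21.2%, 7.51%, 20.8% and 6.43% for Tcf7, 14.6%, 7.32%, 15.4% and 10.2% for Slamf6 and 55.0%, 73.7%, 62.4% and 77.8% for Tox.

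CD8 T-like cells of the anti-PD-1 library were compared with those of the IgG library. The cytotoxic effector list was higher with anti-PD-1 and the progenitor and memory list was lower. Gzmf (1364 against 57.4 CPM, ratio 23.8, 21.7 to 26.1), Gzmc (1080.2 against 85.4 CPM, ratio 12.6, 11.7 to 13.6), Gzmd (439 against 41.7 CPM, ratio 10.5, 9.45 to 11.8) and Gzme (415 against 55.7 CPM, ratio 7.44, 6.77 to 8.20), which encode serine proteases of cytotoxic granules, were all higher, and so was Gzmb (2463 against 813 CPM, ratio 3.03, 2.95 to 3.11). Tcf7 (11.6 against 60.01 CPM, ratio 0.193, 0.159 to 0.232) and S1pr1 (13.6 against 71.2 CPM, ratio 0.191, 0.160 to 0.227), the receptor that lets T cells leave tissues, were lower. 12 of the 23 measured members of the cytotoxic effector list were higher by 1.5-fold or more and 2 were lower. The list had a median log2 ratio of 0.59 at percentile 100 of 10000 random lists matched on expression. In the progenitor and memory list 12 of 16 measured members were lower by that size and 0 were higher (median -1.20, percentile 0). Such percentiles describe these libraries and are not tests of the treatment. A number given after a gene with an interval and no unit is the ratio to the library it was compared with.

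Members of the other lists added detail. Gzmk (74.4 against 147 CPM, ratio 0.506, 0.464 to 0.551), a granzyme of early effector and memory cells, and the chemokine Ccl4 (357 against 519 CPM, ratio 0.688, 0.660 to 0.718) were lower in spite of the list's median. Ccl9, which encodes a chemokine, was at 73.9 against 6.06 CPM, a ratio of 12.2 (9.20 to 16.5). Among T cell receptor response genes, with a median of 0.20 at percentile 99.7, the transcription factor Irf8 (532 against 223 CPM, ratio 2.38, 2.26 to 2.51) and the costimulatory receptor Tnfrsf9 (614 against 438 CPM, ratio 1.40, 1.35 to 1.46) were higher. The early activation marker Cd69 (45.8 against 61.9 CPM, ratio 0.740, 0.656 to 0.836) was lower. The inhibitory receptor list had a median of 0.18 at percentile 99.2. In it Havcr2 (147 against 102 CPM, ratio 1.44, 1.32 to 1.56), encoding TIM-3, was higher and Tox (194 against 249 CPM, ratio 0.778, 0.733 to 0.825) was lower. Type I interferon genes were higher (6 of 19 by 1.5-fold or more, median 0.49 at percentile 100). Among them were Ifi27l2a (660.0 against 402 CPM, ratio 1.64, 1.58 to 1.71) and Isg20 at 1.73 (1.49 to 2.00). The T cell cluster led by Ifit1 and Ifit3 fell below the CD8 minimum and was not part of these cells. The hypoxia and glycolysis list had a median of 0.46 at percentile 100. Higher were Hilpda (385 against 231 CPM, ratio 1.67, 1.58 to 1.76), a lipid droplet protein induced by low oxygen, and the glycolytic enzyme Aldoa at a ratio of 1.46 (1.42 to 1.503). The chemokine receptor list had a median of -0.47 at percentile 0. The lymph node homing receptor Ccr7 (51.1 against 106 CPM, ratio 0.480, 0.433 to 0.532) was lower and Cxcr6 (412 against 332 CPM, ratio 1.24, 1.19 to 1.30), a receptor of tissue T cells, was higher. Spp1, encoding osteopontin, was at 405 against 154 CPM. The cluster led by Cd8a, Cd8b1 and Tff1 held the most CD8 T-like cells in the IgG and anti-PSGL-1 libraries, and the cluster led by Gzmf and Serpine2 in the anti-PD-1 and combination libraries. Without the cluster led by Dapl1, S1pr1 and Lef1, which was naive-like, the progenitor and memory median was -0.70.

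**Figure D2:**
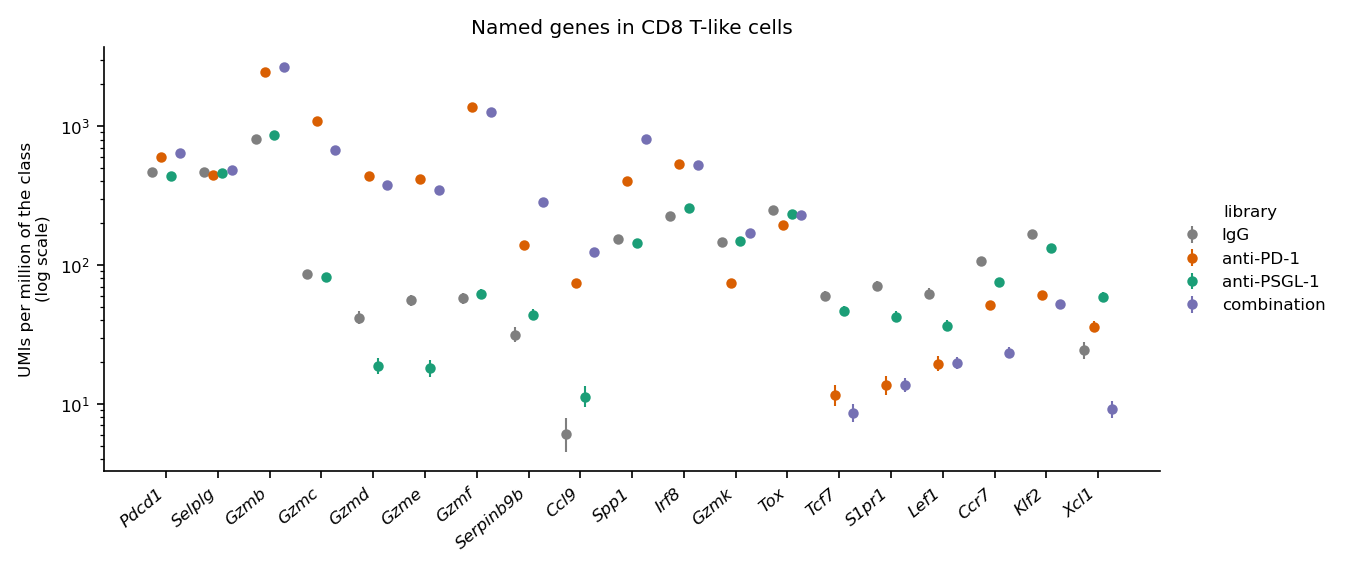
CPM (log axis) of selected genes in CD8 T-like cells of each library, as points with exact 95% Poisson intervals that cover counting error only. Gzmf stands at 1364 CPM with anti-PD-1 and 1254 CPM with the combination against 57.4 CPM with IgG, and Tcf7 is lower in both libraries than with IgG.

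In macrophage- and monocyte-like cells of the anti-PD-1 library, genes induced by interferons were higher than with IgG. Nos2 (202 against 26.8 CPM, ratio 7.53, 6.68 to 8.50), the inducible nitric oxide synthase, Iigp1 (210.3 against 31.7 CPM, ratio 6.64, 5.95 to 7.43), an immunity-related GTPase, and Irg1 (322 against 71.4 CPM, ratio 4.51, 4.18 to 4.87), the enzyme that makes itaconate, were furthest above IgG by the naming rule. Higher too was Socs1 (295 against 72.7 CPM, ratio 4.06, 3.76 to 4.38), a feedback inhibitor of cytokine signalling. 20 of 21 measured type I interferon genes were higher by 1.5-fold or more and 0 were lower (median 0.94 at percentile 100). Of the interferon-gamma and antigen presentation list, 16 of 23 genes were higher by that size (median 1.02 at percentile 100). The eosinophil chemoattractant Ccl24 (13.3 against 75.7 CPM, ratio 0.176, 0.1502 to 0.204), the mannose receptor Mrc1 (38.8 against 106 CPM, ratio 0.366, 0.332 to 0.404) and the lipid carrier Apoe (1477 against 2585 CPM, ratio 0.571, 0.562 to 0.581) were lower. Arg1, encoding arginase, stood at 362 against 315 CPM and the complement gene C1qb at 935 against 978 CPM. The tumour macrophage list as a whole had a median of -0.028 at percentile 41.6, and within it Gpnmb (146 against 73.3 CPM, ratio 1.99, 1.84 to 2.16), a glycoprotein of lipid-laden macrophages, was higher. The inflammation list had a median of 0.46 at percentile 100, with Tnf (383 against 149 CPM, ratio 2.56, 2.43 to 2.71) higher and the neutrophil chemoattractant Cxcl3 (60.2 against 110.2 CPM, ratio 0.547, 0.502 to 0.596) lower. Other interferon genes above IgG were Oasl1 at 2.21 (2.00 to 2.43) and Ifit2 at 2.14 (1.96 to 2.34), and the transcription factor Irf8 was at 2.52 (2.41 to 2.63). Cell cycle genes were lower (14 of 20 by 1.5-fold or more, median -0.88 at percentile 0), although Pcna, the replication clamp, was at 1.42 (1.28 to 1.58). The cell cycle median was -0.98 in macrophage-like and -0.41 in monocyte-like cells alone, where 6 members were measured. The neutrophil transcripts S100a8 (10.6 against 52.7 CPM, ratio 0.202, 0.169 to 0.240) and S100a9 (5.15 against 51.1 CPM, ratio 0.101, 0.0788 to 0.127) were lower in the library where neutrophil-like cells were fewest. Polr2l, a subunit of RNA polymerase II, was at 4.198 (3.87 to 4.56). All 10 genes named by size kept their direction in macrophage-like and in monocyte-like cells taken apart. Among monocyte-like cells, the cluster led by Chil3, Lyz2 and Hp was the larger with IgG and anti-PD-1, and the cluster with Ace and Treml4 among its leading genes was the larger in the other libraries.

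**Figure D3:**
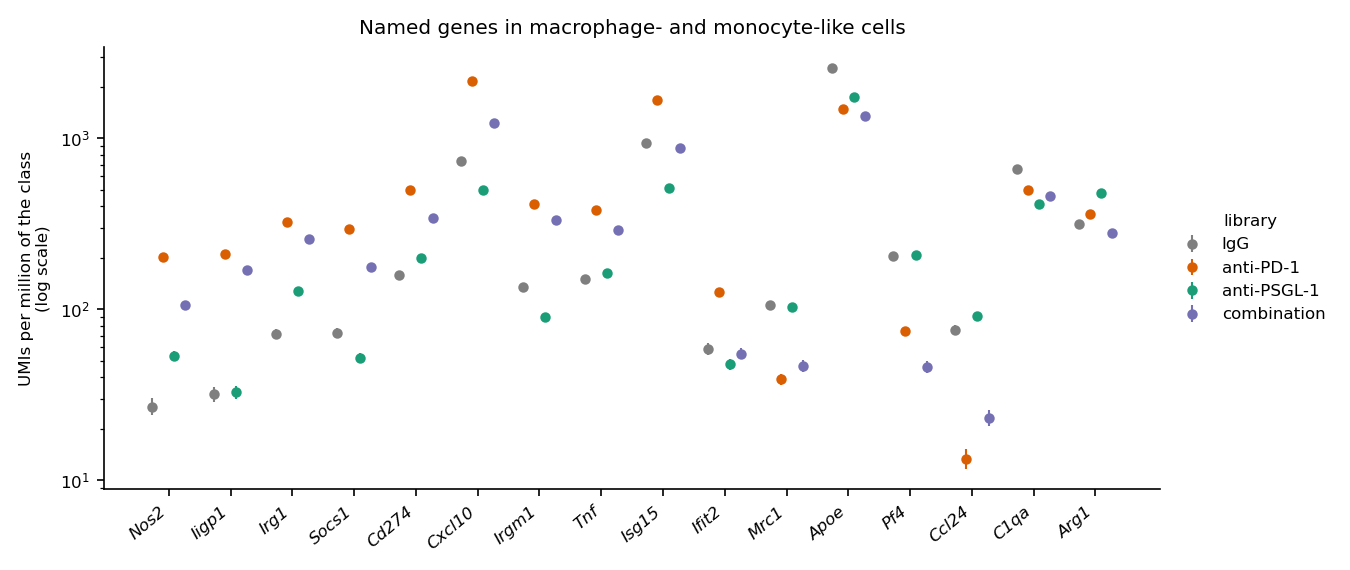
CPM (log axis) of selected genes in macrophage- and monocyte-like cells of each library, as points with exact 95% Poisson intervals that cover counting error only. Nos2 and Iigp1 are highest with anti-PD-1, next with the combination, and Mrc1 is lower in both than with IgG or anti-PSGL-1.

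The anti-PSGL-1 library was compared with the IgG library. Its CD8 T-like cells held Gzmf at 61.9 against 57.4 CPM and Gzmc at 81.3 against 85.4 CPM, so the higher levels of these genes in the anti-PD-1 library were not seen here. The progenitor and memory list was lower, with a median of -0.49 at percentile 0 and 5 of 16 members lower by 1.5-fold or more. The cytotoxic effector list had a median of 0.028 at percentile 94.5, with 1 member higher and 2 lower by that size and a mean of -0.029. That median was 0.26 with cells holding Mki67 or Top2a UMIs left out and 0.11 with each cell weighing the same. Cx3cr1 (56.6 against 25.5 CPM, ratio 2.22, 1.90 to 2.60), the fractalkine receptor of effector cells, and Xcl1 (59.2 against 24.2 CPM, ratio 2.44, 2.09 to 2.87), a chemokine that attracts cDC1, were higher. Gzme (18.1 against 55.7 CPM, ratio 0.325, 0.275 to 0.383) and Areg (51.3 against 156 CPM, ratio 0.329, 0.298 to 0.363), a growth factor of the epidermal growth factor family, were lower.

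Lower members of the progenitor list were Lef1 (36.6 against 62.3 CPM, ratio 0.588, 0.516 to 0.670), a partner of TCF-1, S1pr1 (42.4 against 71.2 CPM, ratio 0.596, 0.528 to 0.672) and Ccr7 (75.8 against 106 CPM, ratio 0.712, 0.648 to 0.782). Without the naive-like cluster the list's median was -0.041 and the S1pr1 log2 ratio was 0.024. Gzma (161 against 109 CPM, ratio 1.47, 1.36 to 1.60) was higher while the NK receptor chain Klrd1 (327 against 431 CPM, ratio 0.757, 0.724 to 0.793) and the chemokine Ccl3 (378 against 495 CPM, ratio 0.763, 0.731 to 0.796) were lower. T cell receptor response genes had a median of 0.27 at percentile 100, with higher Dusp2 (368 against 277 CPM, ratio 1.33, 1.26 to 1.40), a phosphatase induced by activation, and Tnfrsf9 (535 against 438 CPM, ratio 1.22, 1.17 to 1.27). The chemokine receptor list had a median of 0.28 at percentile 100, led by Ccr2 (61.3 against 34.7 CPM, ratio 1.77, 1.54 to 2.03). In the inhibitory list, whose median was -0.026 at percentile 60.8 and mean 0.0047, the inhibitory receptor Lag3 (164 against 224 CPM, ratio 0.736, 0.690 to 0.785) was lower and the ectoenzyme Entpd1 (58.9 against 46.1 CPM, ratio 1.28, 1.13 to 1.45), which encodes CD39, was higher. Interferon genes went both ways: Ifi27l2a (745 against 402 CPM, ratio 1.85, 1.78 to 1.93) was higher and Isg15 (42.2 against 56.3 CPM, ratio 0.750, 0.659 to 0.852), a ubiquitin-like modifier, was lower, and the type I list had a median of 0.12 at percentile 97.6. Cdkn1a, the cell cycle inhibitor p21, was at 1.94 (1.74 to 2.17), and Mki67, a marker of dividing cells, at 1.21 (1.14 to 1.29). Erdr1 was at 0.509 (0.456 to 0.567). Cd74 (164 against 136 CPM, ratio 1.21, 1.12 to 1.30), the invariant chain of MHC class II, was higher.

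The type I interferon list in macrophage- and monocyte-like cells had a lower level with anti-PSGL-1 than with IgG, mainly in monocyte-like cells. Its median was -0.30 at percentile 0, with 3 of 21 members lower by 1.5-fold or more and 0 higher. In monocyte-like cells alone the median was -0.81 with 15 members lower, and in macrophage-like cells alone -0.16 with 2 lower. The cluster with Ace and Treml4 held 327 of 610 monocyte-like cells with anti-PSGL-1 and 172 of 578 with IgG. The monocyte-like median thus compares cells of unlike makeup. Isg15 (515 against 942 CPM, ratio 0.546, 0.531 to 0.562) was lower in macrophage-like and in monocyte-like cells. Ifitm1 (92.4 against 195 CPM, ratio 0.473, 0.443 to 0.505), an interferon-induced membrane protein, was lower in macrophage-like cells, at 0.338 (0.312 to 0.367), and higher in monocyte-like cells, at 1.24 (1.08 to 1.43). The other 9 genes named by size had ratios on the same side of 1 in both. The intervals of S100a9, at 1.19 (0.974 to 1.45), and G0s2, at 1.08 (0.798 to 1.46), held 1 in macrophage-like cells, and that of Stmn1, at 0.949 (0.592 to 1.55), in monocyte-like cells. Cxcl10 (498 against 734 CPM, ratio 0.678, 0.658 to 0.6998), a chemokine for CXCR3 on T cells, was lower. The interferon-gamma list had a median of -0.25 at percentile 0, with 0 of 23 members lower by 1.5-fold or more and 1 higher. Nos2 (53.1 against 26.8 CPM, ratio 1.98, 1.73 to 2.27) and Irg1 (127 against 71.4 CPM, ratio 1.78, 1.64 to 1.94) were higher. The complement genes C1qa (411 against 664 CPM, ratio 0.619, 0.599 to 0.640) and C1qb (613 against 978 CPM, ratio 0.627, 0.610 to 0.645) were lower, and Arg1 (478 against 315 CPM, ratio 1.52, 1.46 to 1.58), the arginine-degrading enzyme of suppressive myeloid cells, was higher. Inflammation genes had a median of 0.39 at percentile 100 with Cxcl2 (5887 against 3755 CPM, ratio 1.57, 1.55 to 1.59), a neutrophil chemoattractant, and the median was 0.17 in macrophage-like and 0.95 in monocyte-like cells alone. Hypoxia genes had a median of 0.22 at percentile 99.99, which was 0.24 in macrophage-like and 0.81 in monocyte-like cells alone. Among them were Egln3 (96.1 against 61.1 CPM, ratio 1.57, 1.44 to 1.72), an oxygen-sensing hydroxylase, and Ero1l (402 against 282 CPM, ratio 1.42, 1.36 to 1.49). Cell cycle genes were lower (14 of 20 by 1.5-fold or more, median -0.75 at percentile 0), as in Stmn1 (27.2 against 50.2 CPM, ratio 0.542, 0.478 to 0.616). This median was -0.74 in macrophage-like and -0.038 in monocyte-like cells alone, where 8 members were measured. The integrin chain Itgal (218 against 139 CPM, ratio 1.56, 1.47 to 1.66) was higher and the heat shock gene Hspa1a (854 against 1297.5 CPM, ratio 0.658, 0.643 to 0.674) was lower. The neutrophil transcripts S100a8 3.67 (3.36 to 4.02), S100a9 3.53 (3.23 to 3.87) and G0s2 2.79 (2.42 to 3.22) were higher here, although neutrophil-like cells held 3.84% against 5.14% with IgG. With doublets kept the S100a9 log2 ratio was -0.043. The ligand of PD-1, Cd274 (199 against 159 CPM, ratio 1.25, 1.18 to 1.32), was higher.

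The combination library was compared with the IgG library for what differed when both antibodies were given. In CD8 T-like cells the cytotoxic effector list was again higher and the progenitor and memory list lower. Gzmf (1254 against 57.4 CPM, ratio 21.9, 20.0 to 24.0), Gzmd (378 against 41.7 CPM, ratio 9.06, 8.14 to 10.1), Gzmc (677 against 85.4 CPM, ratio 7.92, 7.35 to 8.55) and Gzmb (2671 against 813 CPM, ratio 3.28, 3.202 to 3.37) were higher. Gzma at 1.94 (1.81 to 2.08) and Gzmk at 1.16 (1.09 to 1.24) differed less. Higher too were Serpinb9b (284 against 31.5 CPM, ratio 9.03, 7.98 to 10.3), a serine protease inhibitor, and the chemokine Ccl9 (125 against 6.06 CPM, ratio 20.6, 15.6 to 27.7). Tcf7 (8.60 against 60.01 CPM, ratio 0.143, 0.120 to 0.170), S1pr1 (13.8 against 71.2 CPM, ratio 0.194, 0.168 to 0.223), Ccr7 (23.3 against 106 CPM, ratio 0.219, 0.196 to 0.245) and Klf2 (52.6 against 166 CPM, ratio 0.316, 0.292 to 0.342), a factor of quiescent T cells, were lower. The cytotoxic list had 14 of 23 members higher by 1.5-fold or more and 1 lower (median 0.69 at percentile 100). The progenitor list had 14 of 16 lower and 0 higher (median -1.61 at percentile 0). Without the naive-like cluster the progenitor median was -0.77.

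Interferon-gamma genes had 10 members higher and 5 lower by 1.5-fold or more out of 21 (median 0.56 at percentile 100). Cxcl10 (67.6 against 17.1 CPM, ratio 3.95, 3.33 to 4.73) and the GTPase Igtp (132 against 59.9 CPM, ratio 2.20, 2.00 to 2.42) were higher. The MHC class II genes Cd74 (45.22 against 136 CPM, ratio 0.333, 0.305 to 0.363) and H2-Ab1 (19.7 against 52.3 CPM, ratio 0.376, 0.328 to 0.431), which are abundant in myeloid cells, were lower. The type I list had a median of 0.49 at percentile 100, with Zbp1 (153 against 83.8 CPM, ratio 1.82, 1.68 to 1.98), a nucleic acid sensor. Inhibitory genes had a median of 0.23 at percentile 99.6, with Lag3 (339 against 224 CPM, ratio 1.52, 1.44 to 1.59) and Entpd1 (72.5 against 46.1 CPM, ratio 1.57, 1.41 to 1.76) higher and Tox (230.5 against 249 CPM, ratio 0.926, 0.880 to 0.975) slightly lower. Irf8 (526 against 223 CPM, ratio 2.36, 2.24 to 2.48) and Tnfrsf9 at 1.47 (1.42 to 1.53) were higher among T cell receptor response genes (median 0.19 at percentile 97.8). The hypoxia and glycolysis list had a median of 0.34 at percentile 100, including Aldoa at 1.51 (1.46 to 1.55) and Hilpda at 1.62 (1.54 to 1.71). Spp1 (808 against 154 CPM, ratio 5.24, 4.95 to 5.54) exceeded the CPM of the same gene in macrophage- and monocyte-like cells of this library, 693. Areg (295 against 156 CPM, ratio 1.89, 1.78 to 2.01) was higher and Ikzf2 (285 against 334 CPM, ratio 0.853, 0.815 to 0.892), encoding Helios, was lower within the regulatory T cell programme list (median 0.27 at percentile 99.6). The signalling regulator Rgs10 was at 0.294 (0.253 to 0.341).

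In macrophage- and monocyte-like cells of the combination library, interferon-gamma genes were higher than with IgG while the type I list was near its IgG level. 15 of 23 interferon-gamma genes were higher by 1.5-fold or more and 0 lower (median 0.75 at percentile 100), and the type I median was -0.064 at percentile 4.55 (mean 0.024; 0.050 in macrophage-like and -0.29 in monocyte-like cells alone). Iigp1 (170.3 against 31.7 CPM, ratio 5.38, 4.80 to 6.03), Nos2 (106 against 26.8 CPM, ratio 3.95, 3.48 to 4.49) and Irg1 (259 against 71.4 CPM, ratio 3.63, 3.36 to 3.92) were higher, with Tnf (291 against 149 CPM, ratio 1.94, 1.84 to 2.06) and Irf8 (487 against 240.2 CPM, ratio 2.03, 1.94 to 2.12). Mrc1 (46.5 against 106 CPM, ratio 0.439, 0.397 to 0.484), Apoe (1356 against 2585 CPM, ratio 0.525, 0.515 to 0.535), Ccl24 (23.1 against 75.7 CPM, ratio 0.305, 0.267 to 0.348) and Pf4 (46.1 against 205 CPM, ratio 0.224, 0.205 to 0.245), a chemokine of resident macrophages, were lower, and the tumour macrophage median was -0.35 at percentile 0. That median was -0.23 in macrophage-like and 0.20 in monocyte-like cells alone. Cell cycle genes were again lower (14 of 20, median -0.79 at percentile 0), with a median of -0.72 in macrophage-like and -0.062 in monocyte-like cells alone, where 7 members were measured. The integrin chains Itga4 (263 against 152 CPM, ratio 1.73, 1.63 to 1.83) and Itgal (239 against 139 CPM, ratio 1.71, 1.61 to 1.82) were higher, and Cxcl3 (45.8 against 110.2 CPM, ratio 0.416, 0.376 to 0.458) and the heat shock genes Hspa1a at 0.437 (0.425 to 0.449) and Hspa1b at 0.456 (0.439 to 0.474) were lower. These 3 were lower in macrophage-like cells alone but not in monocyte-like cells alone, where Hspa1a was at 1.44 (1.28 to 1.63), Hspa1b at 2.03 (1.73 to 2.39) and Cxcl3 at 1.27 (0.904 to 1.81). Ly6i, of the Ly6 surface protein family, was at 3.71 (3.43 to 4.01). The S100a9 ratio was 4.31 (3.93 to 4.72), although neutrophil-like cells held 2.27% against 5.14% with IgG. This ratio turned with the treatment of doublets: with doublets kept its log2 ratio was -2.44. The ratio was 0.163 (0.105 to 0.245) in macrophage-like cells alone and 4.28 (3.85 to 4.76) in monocyte-like cells alone. The other genes named by size kept their direction in both.

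**Figure D4:**
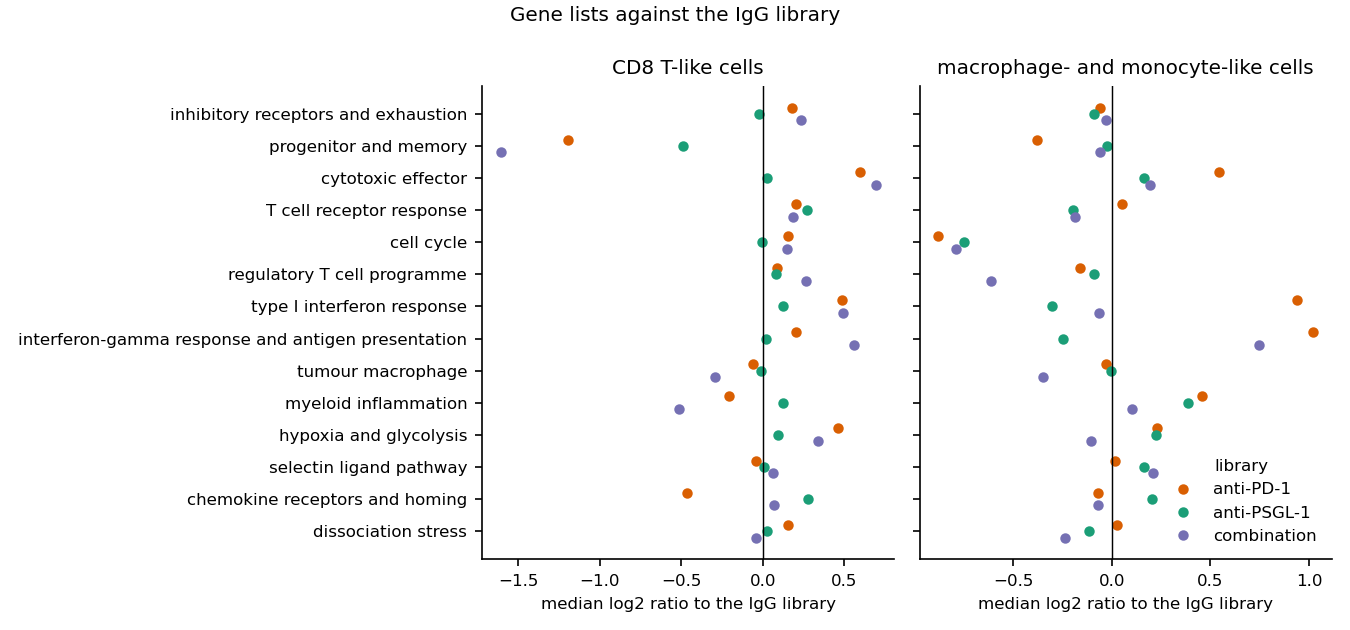
Median log2 ratio to IgG of each fixed gene list (log2 axis) in CD8 T-like and in macrophage- and monocyte-like cells of the treated libraries. The progenitor and memory list lies at -1.20 and -1.61 in CD8 T-like cells with anti-PD-1 and the combination, and the interferon-gamma list at 1.02 and 0.75 in macrophage- and monocyte-like cells.

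The combination library was compared with the anti-PD-1 library for what differed when anti-PSGL-1 was added. In CD8 T-like cells, Gzmk (171 against 74.4 CPM, ratio 2.30, 2.14 to 2.47) was higher with the combination and Gzmc (677 against 1080.2 CPM, ratio 0.627, 0.612 to 0.642) and Gzme (347 against 415 CPM, ratio 0.837, 0.807 to 0.867) were lower. The cluster led by Cd8b1 and Gzmk held 29.4% of CD8 T-like cells with the combination and 12.7% with anti-PD-1, and the cluster led by Gzmf and Serpine2 30.1% and 37.9%. Ccl5 (7602 against 4764 CPM, ratio 1.60, 1.58 to 1.61) and Ccl3 (538 against 366 CPM, ratio 1.47, 1.42 to 1.52), chemokines secreted by effector T cells, were higher. Interferon-gamma genes had a median of 0.37 at percentile 100, with Igtp (132 against 69.4 CPM, ratio 1.90, 1.76 to 2.05) and the guanylate-binding protein Gbp2 (71.6 against 39.6 CPM, ratio 1.81, 1.63 to 2.01) higher. The type I median was -0.22 at percentile 0.0400 and Ifi27l2a (452 against 660.0 CPM, ratio 0.685, 0.665 to 0.706) was lower. Pdcd1 and Selplg were close, at ratios of 1.06 (1.04 to 1.10) and 1.08 (1.05 to 1.12).

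The cytotoxic list had a median of 0.12 at percentile 98.3 and the inhibitory list 0.091 at percentile 92.7, with a mean of -0.023. Cd160 (119 against 82.5 CPM, ratio 1.45, 1.35 to 1.56), a receptor of exhausted and memory cells, and Tox (230.5 against 194 CPM, ratio 1.19, 1.13 to 1.25) were higher, and Nrn1 (22.6 against 67.2 CPM, ratio 0.337, 0.300 to 0.377) was lower. In the progenitor list, median -0.25 at percentile 0, Ccr7 (23.3 against 51.1 CPM, ratio 0.456, 0.405 to 0.514) and Il7r (32.9 against 53.2 CPM, ratio 0.619, 0.556 to 0.690), the interleukin 7 receptor of memory cells, were lower and Cd27, a costimulatory receptor, was at 1.09 (1.04 to 1.14). Without the naive-like cluster the median was 0.12. Icos (190.1 against 146 CPM, ratio 1.30, 1.23 to 1.38), a costimulatory receptor, Itga4 (219 against 123 CPM, ratio 1.78, 1.68 to 1.89), an integrin chain of homing, and Spp1 (808 against 405 CPM, ratio 1.99, 1.93 to 2.06) were higher. Ifitm1 (13.3 against 64.5 CPM, ratio 0.206, 0.179 to 0.236), Ifitm2 (16.9 against 55.4 CPM, ratio 0.305, 0.267 to 0.347) and Ifitm3 (19.1 against 65.8 CPM, ratio 0.290, 0.257 to 0.328), membrane proteins induced by interferon, were lower. The inflammation list had a median of -0.63 at percentile 0 and the hypoxia list -0.037 at percentile 17.9, with a mean of 0.031.

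Type I interferon genes of macrophage- and monocyte-like cells were lower with the combination than with anti-PD-1 (17 of 21 by 1.5-fold or more, median -0.94 at percentile 0), and the interferon-gamma list differed less (median -0.19 at percentile 0.0700). The dissociation stress list was lower too, with a median of -0.30 at percentile 0.0400 and 4 of 18 members lower and 0 higher by that size. Ifit3 (36.3 against 105 CPM, ratio 0.345, 0.311 to 0.382) and Oasl1 (40.8 against 110.2 CPM, ratio 0.370, 0.335 to 0.408), antiviral effectors, Cxcl10 (1232 against 2169.8 CPM, ratio 0.568, 0.557 to 0.579) and Nos2 (106 against 202 CPM, ratio 0.525, 0.493 to 0.559) were lower. Spp1 (693 against 1275 CPM, ratio 0.544, 0.531 to 0.558) and Gpnmb (71.8 against 146 CPM, ratio 0.492, 0.456 to 0.531) were lower. So were Ccl7 (437 against 876 CPM, ratio 0.499, 0.483 to 0.514), a monocyte chemoattractant, Il7r 0.403 (0.377 to 0.431), Flrt3 0.317 (0.282 to 0.357) and Polr2l 0.281 (0.261 to 0.301). Itgal (239 against 140.3 CPM, ratio 1.70, 1.61 to 1.80) and Itga4 (263 against 184 CPM, ratio 1.43, 1.36 to 1.501) were higher. The neutrophil transcripts S100a8 16.1 (13.8 to 19.0) and S100a9 42.7 (34.3 to 54.0) were higher with the combination, where neutrophil-like cells held 2.27% against 1.08%. In monocyte-like cells alone the ratios were 53.0 (37.4 to 77.7) for S100a8 and 46.5 (35.1 to 63.0) for S100a9. In macrophage-like cells alone they were 1.25 (0.970 to 1.61) and 1.22 (0.708 to 2.09), so no difference was detectable there at this depth. The combination's S100a9 level depends on the treatment of doublets: with doublets kept its log2 ratio to IgG was -2.44.

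The combination library was compared with the anti-PSGL-1 library for what differed when anti-PD-1 was added. In CD8 T-like cells, Gzmf (1254 against 61.9 CPM, ratio 20.3, 18.8 to 21.8), Gzmd (378 against 18.7 CPM, ratio 20.2, 17.7 to 23.2), Gzme (347 against 18.1 CPM, ratio 19.2, 16.7 to 22.1) and Gzmb (2671 against 862 CPM, ratio 3.1003, 3.03 to 3.17) were higher with the combination. Gzmg, a further granzyme, was at 97.3 against 0.0862 CPM, the latter from 1 UMI, a ratio of 1129 (202 to 44618). Lag3 (339 against 164 CPM, ratio 2.06, 1.96 to 2.17) and Pdcd1 1.48 (1.43 to 1.53) were higher, Xcl1 (9.12 against 59.2 CPM, ratio 0.154, 0.131 to 0.181) and Ccr7 (23.3 against 75.8 CPM, ratio 0.308, 0.275 to 0.344) were lower, and Selplg was at 1.04 (1.01 to 1.08). The cytotoxic median was 0.52 at percentile 100, the inhibitory median 0.36 at percentile 99.95 and the progenitor median -1.11 at percentile 0, with 14 of 16 members lower by 1.5-fold or more. 12 of 21 interferon-gamma genes were higher and 5 lower by that size (median 0.63 at percentile 100). The lower ones included Cd74 (45.22 against 164 CPM, ratio 0.275, 0.254 to 0.298), H2-Aa 0.243 (0.210 to 0.282) and H2-Eb1 0.258 (0.223 to 0.298). Areg (295 against 51.3 CPM, ratio 5.75, 5.29 to 6.27), Spp1 (808 against 144 CPM, ratio 5.62, 5.35 to 5.92), Ccl9 (125 against 11.3 CPM, ratio 11.1, 9.27 to 13.3), Irf8 (526 against 255.7 CPM, ratio 2.06, 1.98 to 2.14) and the glycolytic enzyme Gapdh (2764 against 1904 CPM, ratio 1.45, 1.43 to 1.47) were higher. Cxcr4 (40.2 against 84.3 CPM, ratio 0.477, 0.435 to 0.523), a homing receptor, Maf (28.5 against 58.0 CPM, ratio 0.492, 0.440 to 0.550), a transcription factor, and Cd69 (54.4 against 80.3 CPM, ratio 0.677, 0.621 to 0.739) were lower, and the chemokine receptor list had a median of -0.44 at percentile 0. In the type I list, median 0.15 at percentile 81.6, Isg15 (89.7 against 42.2 CPM, ratio 2.13, 1.92 to 2.35) and Zbp1 2.09 (1.94 to 2.26) were higher and Ifi27l2a 0.607 (0.590 to 0.625) was lower.

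Macrophage- and monocyte-like cells of the combination library had higher interferon-gamma genes than those of the anti-PSGL-1 library (17 of 23 by 1.5-fold or more, median 0.97 at percentile 100) and a type I median of 0.37 at percentile 99.99. Iigp1 (170.3 against 32.6 CPM, ratio 5.23, 4.75 to 5.76), Irgm1 (331 against 90.0 CPM, ratio 3.68, 3.46 to 3.90), Socs1 (178 against 51.6 CPM, ratio 3.44, 3.18 to 3.73) and Batf2 (67.1 against 16.8 CPM, ratio 4.005, 3.49 to 4.61), a transcription factor induced by interferon, were higher, with Zbp1 1.97 (1.89 to 2.05) and Fam26f 3.31 (3.12 to 3.51). Pf4 (46.1 against 208 CPM, ratio 0.222, 0.203 to 0.242), Ccl24 (23.1 against 91.0 CPM, ratio 0.254, 0.224 to 0.288), Ccl8 (93.6 against 266 CPM, ratio 0.352, 0.330 to 0.375), Mrc1 0.451 (0.410 to 0.495) and Cxcl3 0.290 (0.265 to 0.317) were lower, except that Ccl24 was at 1.13 (0.778 to 1.64) in monocyte-like cells alone, while C1qb 1.35 (1.31 to 1.38) was higher. Klrk1 (61.2 against 22.5 CPM, ratio 2.72, 2.40 to 3.09), the NKG2D receptor gene of cytotoxic lymphocytes, was higher, and Egln3 0.550 (0.502 to 0.602) and Spp1 0.520 (0.507 to 0.533) were lower.

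The remaining lists against IgG in CD8 T-like cells are given as medians of the log2 ratio in the order anti-PD-1, anti-PSGL-1 and combination. The cell cycle list had 0.15 at percentile 98.7, -0.0075 at percentile 83.7 and 0.15 at percentile 94.4. The regulatory T cell programme list had 0.086 at percentile 78.4, 0.083 at percentile 91.9 and 0.27 at percentile 99.6. The tumour macrophage list had -0.059 at percentile 20.3, -0.0094 at percentile 53.3 and -0.29 in the lower tail of the random lists. The myeloid inflammation list had -0.21 at percentile 5.29, 0.12 at percentile 86.0 and -0.52 at percentile 0.0400. The selectin ligand pathway list had -0.041 at percentile 16.8, 0.0093 at percentile 79.7 and 0.064 at percentile 60.9. The dissociation stress list had 0.16 in the upper tail of the random lists, 0.025 at percentile 85.6 and -0.044 at percentile 6.61. The interferon-gamma list had 0.20 at percentile 99.9 with anti-PD-1 and 0.022 at percentile 89.1 with anti-PSGL-1, the hypoxia list 0.090 at percentile 97.7 with anti-PSGL-1, and the chemokine receptor list 0.069 at percentile 66.0 with the combination. Medians and means differed in sign with anti-PD-1 for the regulatory T cell programme (mean -0.083) and inflammation (mean 0.044). They did so with anti-PSGL-1 for the cytotoxic and inhibitory lists, cell cycle (mean 0.016), the regulatory programme (mean -0.094), tumour macrophage (mean 0.19), selectin (mean -0.014) and dissociation lists (mean -0.014). With the combination they did so for tumour macrophage (mean 0.073), selectin (mean -0.13) and chemokine receptors (mean -0.22). With cells holding Mki67 or Top2a UMIs left out, the cell cycle median was -0.088 with anti-PD-1 and -0.16 with the combination. Without the naive-like cluster the combination's cell cycle median was -0.029 and its dissociation median 0.083. Within the selectin ligand pathway, Itgb2, the common beta chain of leukocyte integrins, was at 1.38 (1.31 to 1.47) with anti-PD-1 and 1.22 (1.15 to 1.29) with anti-PSGL-1. Capg, an actin-capping protein in the regulatory programme list, was at 1.81 (1.71 to 1.92) with anti-PD-1.

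The remaining lists in macrophage- and monocyte-like cells, in the same order, were as follows. The inhibitory receptors and exhaustion list had -0.061 at percentile 40.7, -0.090 at percentile 22.2 and -0.029 at percentile 30.5. The progenitor and memory list had -0.38 at percentile 0.600, -0.026 at percentile 43.8 and -0.061 at percentile 30.4. The cytotoxic effector list had 0.55 at percentile 100, 0.17 at percentile 99.0 and 0.19 at percentile 98.4. Its members include Tnf, Ccl3 and Ccl4, at 149, 397 and 1062 CPM in these cells with IgG, and granzymes such as Gzmc at 0.718 CPM. These medians are therefore not read as a cytotoxic programme of these cells. The T cell receptor response list had 0.052 at percentile 77.2, -0.20 at percentile 0.220 and -0.19 at percentile 0.220. The regulatory T cell programme list had -0.16 at percentile 18.1, -0.089 at percentile 19.5 and -0.61 at percentile 0. The selectin ligand pathway list had 0.016 at percentile 60.8, 0.16 at percentile 99.4 and 0.21 at percentile 99.3. The chemokine receptors and homing list had -0.072 at percentile 39.6, 0.20 at percentile 98.9 and -0.070 at percentile 19.5. The dissociation stress list had 0.025 at percentile 63.1, -0.12 at percentile 5.61 and -0.24 at percentile 0.0800. The hypoxia list had 0.23 at percentile 99.0 with anti-PD-1 and -0.11 at percentile 1.34 with the combination, the tumour macrophage list -0.0050 at percentile 66.1 with anti-PSGL-1 (mean 0.17), and the inflammation list 0.10 at percentile 92.7 with the combination. The inflammation median with the combination was 0.091 in macrophage-like and 0.46 in monocyte-like cells alone. Several of these lists differed in sign between the summed and the separate classes. With anti-PD-1 the medians in macrophage-like and in monocyte-like cells alone were 0.032 and 0.034 for inhibitory receptors and exhaustion, -0.39 and 0.14 for progenitor and memory, -0.16 and 0.19 for regulatory T cell programme, -0.10 and 0.13 for chemokine receptors and homing and -0.053 and 0.30 for tumour macrophage. With anti-PSGL-1 they were 0.077 and 0.34 for inhibitory receptors and exhaustion, -0.33 and 0.48 for progenitor and memory, -0.25 and 0.045 for T cell receptor response, 0.011 and -0.22 for regulatory T cell programme, -0.17 and 0.31 for dissociation stress and 0.031 and 0.35 for tumour macrophage, and with the combination -0.046 and 0.15 for inhibitory receptors and exhaustion, -0.15 and 0.35 for progenitor and memory, -0.29 and 0.14 for T cell receptor response, -0.48 and 0.16 for regulatory T cell programme, 0.030 and 0.039 for chemokine receptors and homing, -0.23 and 0.013 for dissociation stress and -0.072 and 0.43 for hypoxia and glycolysis. Some directions turned with the processing. The anti-PD-1 progenitor median was 0.081 with at least 100 UMIs per member. The anti-PSGL-1 cytotoxic median was -0.10 and the combination's hypoxia median 0.14 with clusters weighing the same, and the anti-PSGL-1 selectin median was -0.015 with each cell weighing the same. Means differed in sign from the medians for the T cell receptor response with anti-PD-1 (mean -0.013) and the regulatory programme with anti-PSGL-1 (mean 0.12). Entpd1, which also marks macrophages, was at 1.44 (1.34 to 1.55) with anti-PD-1, and Selplg at 1.16 (1.08 to 1.23) with the combination.

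A further set of genes differed alike in lymphoid and myeloid cells, and their values are uncertain. Gstp1, a glutathione transferase, was at 83.3, 14.0, 71.0 and 72.9 CPM in CD8 T-like and 60.7, 6.68, 60.03 and 63.0 CPM in macrophage- and monocyte-like cells, in the order IgG, anti-PD-1, anti-PSGL-1 and combination. Hist1h2ap, a histone gene, was at 1077, 180.0, 1806 and 764 CPM in CD8 T-like cells, and the glycolytic Pgk1 at 76.4, 28.6, 86.0 and 96.1 CPM and Eno1 at 428, 278, 453 and 551 CPM. In its last 500 bases, Hist1h2ap shared 93.1% of its 50-base words with other annotated genes, Gstp1 75.2%, Eno1 75.2% and Pgk1 7.32%. Bcl2a1d (294 against 107 CPM in the combination against anti-PD-1, CD8 T-like) and Rnaset2a (20.2 against 54.8 CPM) shared 87.8% and 87.6%. Gapdh shared 39.2%, Ifitm2 41.9% and Erdr1 33.3%, so their values are uncertain too. For granzymes the shares were lower: 20.6% for Gzmd, 18.2% for Gzme, 14.4% for Gzmg and 7.10% for Gzmf. Granzymes were also among the genes that differed alike by 2-fold or more in CD8 T-like, NK-like and macrophage- and monocyte-like cells. Those counted were Gzme with anti-PD-1 against IgG, Gzmb and Gzmc with the combination against IgG, and Gzmd and Gzmf with the combination against anti-PSGL-1. Genes with 0 UMIs in either library of a class, or fewer than 20 in both together, were not counted. Gzmf and Gzmd were thereby left out against IgG. In NK-like cells Gzmf was at 0, 7.90, 6.86 and 60.4 CPM and Gzmd at 0, 64.7, 70.7 and 480 CPM. In macrophage- and monocyte-like cells Gzmf was at 0, 5.22, 0.124 and 3.94 CPM. S1pr1 with the combination against IgG and Irgm1 with the combination against anti-PSGL-1 differed alike in the same way. Macrophage- and monocyte-like cells held Gzmb at 5.29, 12.5, 8.35 and 13.3 CPM and Gzmc at 0.718, 5.03, 2.10 and 1.97 CPM. These granzyme genes lie together on chromosome 14 in mm10, from Gzme at 56117626 to 56120625 and Gzmd at 56129556 to 56132608. They run on through Gzmg at 56156582 to 56159579, Gzmf at 56205263 to 56211417 and Gzmc at 56231441 to 56234656, to Gzmb at 56258838 to 56262260.

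**Figure D5:**
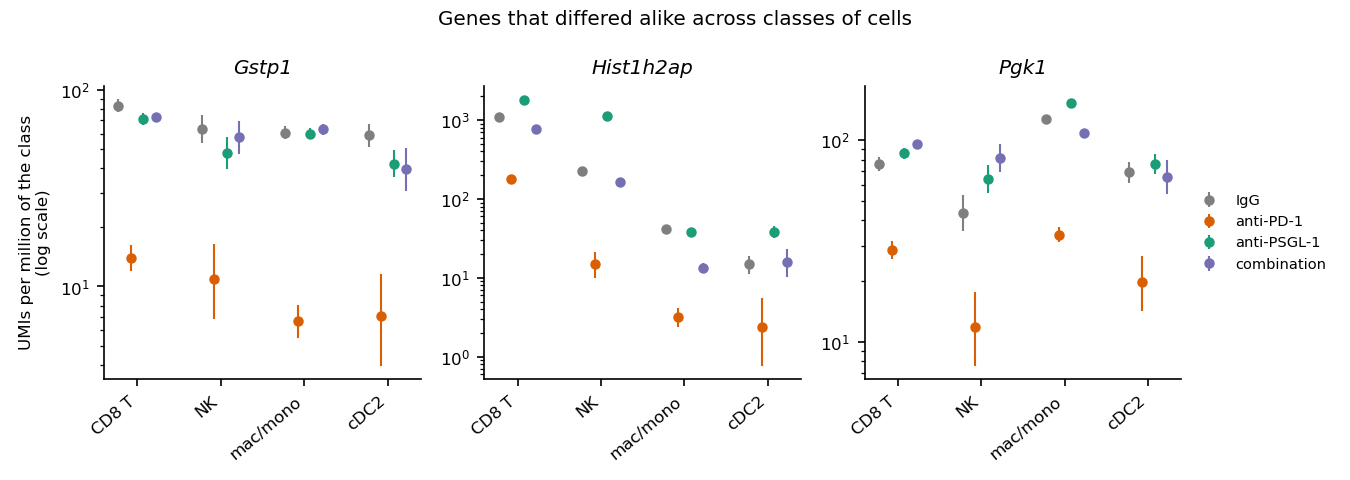
CPM (log axis) of Gstp1, Hist1h2ap and Pgk1 in 4 classes of cells of each library, as points with exact 95% Poisson intervals that cover counting error only. Gstp1 is lowest with anti-PD-1 in every class drawn, at 14.0 CPM in CD8 T-like cells against 71.0 CPM with anti-PSGL-1.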

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

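Both tests of the unnamed cells were chosen only after the result was seen. A cluster that carried no class name, in which Cd209a, Clec10a and Hist1h2ap led, held 1166 barcodes, of which 1085 (93.1%) came from the IgG library. They were 12.4% of the kept IgG barcodes and entered no comparison of genes, though the shares of all classes count them in the total. Without any of the unnamed cells in the total, those of this cluster and of the other unnamed clusters, CD8 T-like cells were 17.3% in place of 15.1% of the IgG library. The median of 2728 UMIs was 0.668 times that of the named IgG cells (4085.5 UMIs). Droplets that had captured 2 or more cells were predicted to hold more. The median cannot decide this, because IgG class medians ran from 1309 UMIs in neutrophil-like to 9481.5 in cDC1-like cells. Droplets with several shallow cells could hold as few, and the highest-scoring likely doublets had already been removed. After thinning to 1000 UMIs 26.6% (23.8 to 29.5) of 955 such barcodes carried a CD3 gene with genes of other lineages, 44.0 times the 0.605% (0.434 to 0.820) of 6778 named cells. This decides nothing, because a class name needed fewer than 25% of cells mixed between lineages and the cluster stood at 64.9%. Droplets of several cells, RNA from other cells and a state of cells particular to the IgG tumour therefore cannot be told apart. With 1 library, the group and the library cannot be separated either.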

How the results depend on the processing

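No paired analysis was possible because each group had 1 library. The alternatives without unnamed cells, without the naive-like cluster and without members that share sequence were chosen after seeing the data. The cause was not tested for any value below unless stated. Shares stayed within their counting interval in 351 comparisons with an alternative and left it in 117. List medians were unmoved in 1016, moved in 227 and reversed in 17. Genes named by size were unmoved in 426, moved in 171 and reversed in 3. Pdcd1 and Selplg moved in 15 and not in 33. The genes that the naming rule picks differed in 19 of the sets made with another low-count filter and were alike in 1. Thinned shares moved in 62 and were unmoved in 2, by construction of the depth. Median-of-ratios scaling subtracted the median log2 ratio of all genes, -0.036 to 0.053, from the log2 ratios of CD8 T-like and macrophage- and monocyte-like cells. Depth limits low genes most, and 1 library per group limits every comparison. With the stricter cell filter, CD8 T-like shares were 18.0% with IgG, 24.0% with anti-PD-1, 23.3% with anti-PSGL-1 and 42.3% with the combination, IgG macrophage- and monocyte-like cells 29.0% and IgG regulatory T-like cells 6.38%. With doublets kept, CD8 T-like cells were 14.2% with IgG and macrophage- and monocyte-like cells 34.1% with anti-PSGL-1. With removal doubled, CD8 T-like cells were 16.2% and 21.2% with IgG and anti-PSGL-1. With classes by marker UMIs per cell, CD8 T-like cells were 17.0% with IgG and 22.7% with anti-PD-1, and macrophage- and monocyte-like cells 44.7%, 33.7% and 35.2% with anti-PD-1, anti-PSGL-1 and the combination. Without unnamed cells in the denominator, IgG had 17.3% CD8 T-like, 30.3% macrophage- and monocyte-like and 6.20% regulatory T-like cells. With subsets by UMIs of Cd8a or Cd8b1, Cd4 and Foxp3, CD8 T-like cells were 72.4%, 53.6% and 82.2% of T-like cells with anti-PD-1, anti-PSGL-1 and the combination.

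In CD8 T-like cells with cells holding Mki67 or Top2a UMIs left out, the log2 medians against IgG were -0.92 (progenitor), 0.77 (cytotoxic) and -0.088 (cell cycle) for anti-PD-1. They were 0.26 (cytotoxic) for anti-PSGL-1, and -1.72 (progenitor), -0.16 (cell cycle) and 0.0022 (dissociation) for the combination. Mki67 and Top2a stand in the cell cycle list themselves, and why its medians turned was not tested. Without the naive-like cluster they were -0.70 (progenitor) and 0.46 (cytotoxic) for anti-PD-1, -0.041 (progenitor) and 0.024 (S1pr1) for anti-PSGL-1. They were -0.77 (progenitor), -0.029 (cell cycle) and 0.083 (dissociation) for the combination, and 0.12 (progenitor) for the combination against anti-PD-1. With each cell weighing the same, progenitor medians were -1.004, -0.64 and -1.78, and cytotoxic medians 0.76 and 0.11 for anti-PD-1 and anti-PSGL-1. As means, the cytotoxic list was 0.84 for anti-PD-1 and 1.01 for the combination. The regulatory programme was -0.083 for anti-PD-1, the progenitor list -0.37 for anti-PSGL-1, the selectin list -0.13 for the combination. The inhibitory and hypoxia lists were -0.023 and 0.031 for the combination against anti-PD-1. With CD8 T-like cells taken by UMIs of Cd8a or Cd8b1, the anti-PSGL-1 progenitor median was -0.34. In macrophage- and monocyte-like cells with doublets kept, the S100a9 log2 ratio was -0.043 for anti-PSGL-1 and -2.44 for the combination, and the combination's interferon-gamma median was 0.81. With clusters weighing the same, interferon-gamma medians were 1.17, -0.17 and 0.70, the anti-PSGL-1 cytotoxic median -0.10, and the combination's hypoxia median 0.14. Medians of the combination against anti-PD-1 were 0.013 in place of -0.15 (tumour macrophage) and 0.082 in place of -0.36 (hypoxia), and against anti-PSGL-1 0.0019 in place of -0.18 (tumour macrophage). With each cell weighing the same, the combination's interferon-gamma median was 0.80 and the anti-PSGL-1 selectin median -0.015. The interferon-gamma means were -0.18 for anti-PSGL-1 and 0.81 for the combination. With at least 100 UMIs per member, the anti-PD-1 progenitor median was 0.081.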

Other observations

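The depth test of the genes that differed alike in several classes, and the test of the progenitor list member by member, were chosen only after the result was seen, and the test without the naive-like cluster uses an alternative added after seeing the data. In NK-like cells, Gzmc stood at 5429 (5324 to 5535) CPM with the combination against 648 (616 to 682) with IgG, 878 (838 to 919.9) with anti-PD-1 and 971 (932 to 1010.3) with anti-PSGL-1, above the CD8 T-like level in each library except anti-PD-1. NK Gzmb was 1004, 1809, 863 and 2622 CPM in the order IgG, anti-PD-1, anti-PSGL-1 and combination, and Gzme 3.53, 50.9, 23.4 and 164 CPM. Cell cycle genes of NK-like cells were lower with anti-PD-1 (13 of 20 by 1.5-fold or more, median -0.73 at percentile 0) and higher with anti-PSGL-1 (18 of 20, median 1.66 at percentile 100) and the combination (13 of 20, median 0.72 at percentile 100). The NK-like cluster with Hist1h2ap among its leading genes held 10 of 795, 4 of 503, 38 of 425 and 8 of 245 NK-like cells in the order IgG, anti-PD-1, anti-PSGL-1 and combination, so these lists compare NK-like cells of unlike makeup. The NK type I interferon medians were 0.76 at percentile 100, -0.11 at percentile 31.5 and 0.28 at percentile 99.6 for anti-PD-1, anti-PSGL-1 and the combination.

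In cDC2-like cells, type I interferon genes were higher with anti-PD-1 (19 of 21 by 1.5-fold or more, median 1.28 at percentile 100) and lower with anti-PSGL-1 (12 of 21, median -0.66 at percentile 0), with the combination at 0.18 at percentile 95.03. The interferon-gamma medians of cDC2-like cells were 0.90 at percentile 100, -0.59 at percentile 0 and 0.41 at percentile 100, and the tumour macrophage list went the other way with each single antibody, at -0.79 at percentile 0 and 0.73 at percentile 100, with the combination at 0.012 at percentile 30.3. Conventional CD4 T-like cells had inhibitory receptor medians of 0.17 at percentile 86.9, -0.067 at percentile 56.4 and 0.48 at percentile 99.9, and cell cycle medians of -0.65 at percentile 0.330, 0.57 at percentile 100 and -0.26 at percentile 9.05. The inhibitory medians rest on 10, 12 and 12 measured members. The cell cycle medians rest on 6, 14 and 7 of 20 members, of which 3 were lower, 7 higher and 1 lower by 1.5-fold or more, so they do not compare the same genes.

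Gstp1, Hist1h2ap and other genes differed alike across classes, with 34 genes at 2-fold or more between anti-PD-1 and IgG in CD8 T-like, NK-like and macrophage- and monocyte-like cells. Depth per cell is argued against as the whole cause. Between cells of the 2 libraries matched on UMIs within each class, 100% (34 of 34) of these genes kept their direction at 1.5-fold or more on average over the classes. Matched median depths were 7828 UMIs with anti-PD-1 and 7781 with IgG in CD8 T-like cells, against 10305 and 4739 before matching. Reads shared between near-identical genes remain, as 21 of the 34 genes (61.8%) shared sequence against 7.37% of 7786 genes, and the size of difference of sharing genes lay at percentile 98.55 of matched lists. With the combination against anti-PD-1 the percentile was 100, with 12 of 16 genes sharing sequence, and for the other comparisons it was 94.75, 56.7 and 44.8 (anti-PSGL-1 and combination against IgG, combination against anti-PSGL-1). A difference in how the anti-PD-1 reads were handled may lie behind it, which was not tested, and no biological explanation was tested for it.

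The progenitor and memory list was lower in CD8 T-like cells of the treated libraries, and a larger share of naive-like cells with IgG is argued against as the whole cause with the combination, since its median was -1.61 with that cluster and -0.77 without it. With anti-PSGL-1 it was -0.49 and -0.041, so a larger share of these cells stays open as the whole cause there, and the cluster left out had list members (S1pr1, Lef1, Tcf7 and Satb1) among its leading genes. RNA from other cells was tested in a pair of ways: summed over the list, macrophage- and monocyte-like cells of the IgG library reached 51.6% of the CD8 T-like level, on the side of that explanation, and this value led to the member-by-member test, in which 11 of 16 members (68.8%) lay below 25% of their CD8 T-like level. Macrophage- and monocyte-like cells held Id3 at 2634%, Klf2 at 139%, Il7r at 118% and Slamf6 at 34.2% of the CD8 T-like level, so such RNA stays open for members of this kind, while Tcf7 was at 2.69%. Both ways looked at macrophage- and monocyte-like cells only, so RNA from lymphoid or dendritic cells stays open for every member, Tcf7 included. An other T cluster with Tcf7 and S1pr1 among its leading genes held 377 cells with IgG and 49 with the combination. A difference in the state of CD8 T cells with the antibodies is a hypothesis that may be followed up, and 1 library per group cannot test it.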
